A study of Homo sapiens with 12 samples.

How the data were processed

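Gene expression was measured by RNA sequencing in 2 human diffuse large B cell lymphoma lines, TMD8 (activated B cell-like) and OCI-Ly7 (germinal centre B cell-like). Each line carried a doxycycline-inducible guide RNA against PRMT5 and was given 20 ng/ml doxycycline for 0, 3 or 6 days, with 2 libraries per day and line (12 libraries in 6 groups). The treatment protocol in the labels names other days than the sample titles, the sample characteristics and the design text; these last 3 name days 0, 3 and 6 and were followed. Per the labels, RNA was taken up with RNeasy Plus mini kits and libraries were made with the Illumina TruSeq RNA Library Prep kit. Per the submitters' processing notes, reads were aligned with HISAT to hg19 and assembled with StringTie, with versions not given in the sources used here. The deposited values are FPKM computed by the authors per library, with 1 table of 25369 rows per line, keyed by gene symbol. The values were not whole numbers and were never negative. Each table held 28 rows with names of the form of dates, which were kept under those names.

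The sum of FPKM per library lay between 397477 and 467844, and 10092 to 11021 genes reached an FPKM of at least 1. The absolute depth was not given in the sources used here. A relative depth was read from the most common ratio between the small values of 2 libraries, with the first day 0 library of each line set to 1. It came to 1.17 for the other TMD8 day 0 library, 0.54 and 0.74 at day 3 and 0.62 and 0.57 at day 6; in OCI-Ly7 it came to 1.29, then 0.91 and 0.89, then 0.81 and 0.77. Values close to 0 in the treated libraries, TMD8 above all, therefore rest on fewer fragments than at day 0. The share of the 45S pre-ribosomal RNA row in all fragments was computed from its FPKM and its length of 13357 nt in RefSeq. Older gene symbols were matched with RefSeq synonyms and a reference list of gene names. The reference annotation (GENCODE v29, on GRCh38) served for overlap between genes. It was of another build than hg19, so no coordinates were printed.

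Differences between days were tested within each line with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for genes with a mean FPKM of at least 1 over the 6 libraries of that line (10456 genes in TMD8, 11016 in OCI-Ly7). The 3 days shared 1 estimate of the spread with 3 residual degrees of freedom per line, moderated with a mean-dependent trend, and p-values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. The difference between the lines, OCI-Ly7 minus TMD8, was tested as a difference of the 2 effects in a fit over the 12 libraries (9688 genes). The gene lists, 25 in number with 466 genes, were written before the data were examined, as were the tests, the groups and the rule for naming genes. They covered the PRMT5 complex, other PRMT genes, B cell receptor signalling, PI3K, AKT and mTOR, NF-kB targets, p53 targets, G1/S and DNA replication, G2/M, G1 cyclins with their kinases and inhibitors, MYC and ribosome biogenesis, the BCL2 family, germinal centre, plasma cell and activated B cell genes, BCL6-repressed genes, interferon response, MHC class II, Sm proteins and splicing factors, the integrated stress and unfolded protein responses, cholesterol synthesis, glycolysis and hypoxia, mitochondrially encoded genes, and markers of T and NK, myeloid, and stromal and epithelial cells. Lists with at least 3 measured genes were tested against the other genes with camera from limma at a preset correlation of 0.01, and again with the correlation estimated from the residuals. Counts within a list were also taken with p-values adjusted over the list alone.

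Genes were named by a rule: in each line, among genes past the threshold and with both libraries of one day beyond both libraries of the other, the 12 with the largest change in each direction for day 6 against day 0, 6 for day 3 against day 0, and 5 for day 6 against day 3. It further named 5 in each direction for the difference between the lines; 8 in each direction past the threshold in both lines at day 6; up to 4 per list and line. A fixed set was always named, including the PRMT5 complex, MYC, BCL6, IRF4, PRDM1, CDKN1A, CCND1, CCND2, CCND3, CD79A, CD79B, BTK, SYK and BCL2. Not every gene that the rule named is printed.

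FPKM adds up to a fixed total per library apart from gene length, so a row that takes more fragments lowers the others. The same tests were therefore repeated after median-ratio scaling, in which each library was divided by the median ratio of its genes to their geometric mean over the line. The other alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, no trend, rescaling to an equal sum per library, a replicate block, a fit of the 2 compared days alone, and leaving out each library in turn. In the last, the remaining library of a group was assumed to vary like the other groups. A further 2 alternatives were chosen after the data were seen: rescaling over the rows left without ribosomal, small RNA and histone rows, and leaving out the second OCI-Ly7 libraries of days 3 and 6 together. The pipeline was tested on simulated data of the same design. With no added shift, it recovered 62.7% of TMD8 genes given a log2 change of 0.5 and 97% of those given 1. In OCI-Ly7 the shares were 7.46% and 86.6%. The changes were given only to genes well above the filter on mean FPKM, and the spread was drawn separately for each gene. Recovery of genes close to the filter was therefore not measured and can be lower. With the treated libraries lowered by 0.3 on the log2 scale, 4979 unchanged genes in TMD8 passed on FPKM as given and 8 after median-ratio scaling. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. Each comparison of days also compared time in culture and doxycycline, since no libraries with doxycycline and a non-targeting guide were used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.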

Results

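PRMT5 transcript was lower after induction of the guide in both lymphoma lines on FPKM as given, along different courses. After scaling between libraries (median-ratio scaling) the loss in TMD8 did not pass the test, and its sign turned at day 6. In TMD8, PRMT5 stood at 64.8 and 60.5 FPKM in the 2 libraries of day 0, at 41.3 and 42.0 at day 3, and at 49.6 and 54.7 at day 6. In OCI-Ly7, PRMT5 stood at 37.9 and 46.9 FPKM at day 0, at 29.3 and 32.1 at day 3, and at 21.0 and 19.2 at day 6. The loss was therefore deepest at day 6 in OCI-Ly7 and at day 3 in TMD8. The transcript level does not measure the protein, and frameshifted transcripts can remain, so the extent of PRMT5 loss was not measured. On the log2 scale PRMT5 changed by -0.58 (SE 0.074) in TMD8 at day 3 (adjusted p = 0.0212) and by -1.04 (SE 0.133) in OCI-Ly7 at day 6 (adjusted p = 0.0345). The OCI-Ly7 change held after median-ratio scaling (-0.89, adjusted p = 0.0284), whereas the TMD8 change at day 3 did not pass (-0.28, adjusted p = 0.147). At day 6 in TMD8, PRMT5 was lower on FPKM as given (-0.26, adjusted p = 0.0262) and turned to 0.10 after median-ratio scaling (adjusted p = 0.201). At day 3 in OCI-Ly7 the change was -0.45 (adjusted p = 0.618). Among the partners of PRMT5, WDR77 fell in OCI-Ly7 from 42.0 ± 0.92 to 26.0 ± 0.36 FPKM (SD, n = 2; log2 change -0.68, adjusted p = 0.0345) and RIOK1 fell by 0.57 (adjusted p = 0.043). In TMD8 WDR77 changed by -0.09 (adjusted p = 0.507), and by 0.26 after median-ratio scaling (adjusted p = 0.058). Leaving out 1 library leaves its group with 1, which changed how many genes passed, to fewer in some comparisons and to more in others. The changes of PRMT5 kept their direction in each such fit, from -0.63 to -0.53 in TMD8 at day 3, -0.33 to -0.19 at day 6, and -1.19 to -0.89 in OCI-Ly7 at day 6, as did WDR77 (-0.70 to -0.65) and RIOK1 (-0.64 to -0.49) in OCI-Ly7. In TMD8 at day 3, PRMT5 no longer passed without the first or second day 0 library (adjusted p = 0.132 and 0.0659) or the first or second day 3 library (adjusted p = 0.0818 and 0.0729). In TMD8 at day 6 it no longer passed without the first or second day 0 library (adjusted p = 0.144 and 0.0518) or the first day 6 library (adjusted p = 0.106). In OCI-Ly7 at day 6 PRMT5 no longer passed without the first or second day 0 library (adjusted p = 0.103 and 0.23) or the first or second day 6 library (adjusted p = 0.0721 and 0.135), and WDR77 and RIOK1 did not pass without the same 4 libraries (adjusted p up to 0.247 and 0.27). Without the filter on mean FPKM the calls of PRMT5, WDR77 and RIOK1 in OCI-Ly7 did not pass either.

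**Figure D1:**
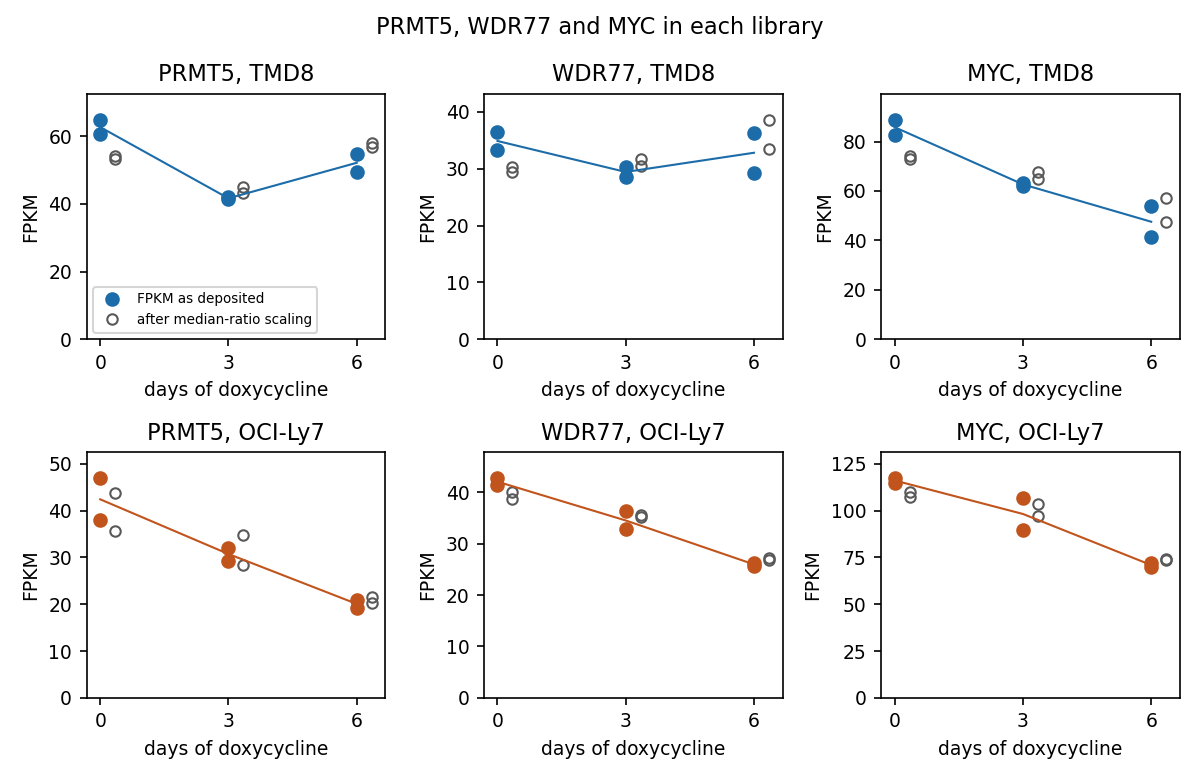
FPKM of PRMT5, WDR77 and MYC in each library of TMD8 and OCI-Ly7 at days 0, 3 and 6. After median-ratio scaling the day 6 change of PRMT5 and of WDR77 in TMD8 turned from negative to positive.

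Most transcripts in treated TMD8 had a lower FPKM than at day 0, and this common shift set the frame for the single genes. The median log2 change over the tested genes was -0.27 at day 3 and -0.31 at day 6 in TMD8, against -0.12 and -0.13 in OCI-Ly7. The 45S pre-ribosomal RNA took 6.98% and 10.6% of the fragments in the TMD8 libraries of day 0, 26.8% and 27.3% at day 3, and 27.1% and 23.5% at day 6; in OCI-Ly7 it took 14.9% and 13.9%, then 19.1% and 27.4%, then 21.5% and 27.0%. Changes are therefore given both on FPKM as given and after median-ratio scaling, which sets them relative to the common shift. In TMD8, 4492 genes passed at day 3 (157 higher, 4335 lower) and 5816 at day 6 (407 higher, 5409 lower). After median-ratio scaling 23 passed at day 3 (15 higher, 8 lower) and 3021 at day 6 (1612 higher, 1409 lower). The share of higher genes among those that passed at day 6 went from 7% to 53.4%, where the scaling itself sets the median change to 0. It was 10.9% after rescaling to an equal sum (457 higher, 3726 lower) and 24.5% after rescaling without ribosomal, small RNA and histone genes (757 higher, 2334 lower). In OCI-Ly7, 16 genes passed at day 3 (8 higher, 8 lower) and 1252 at day 6 (218 higher, 1034 lower), against 13 and 1626 (739 higher, 887 lower) after median-ratio scaling. In TMD8 at day 6, 398 higher and 1409 lower genes passed under both scalings, and in OCI-Ly7 218 higher and 817 lower.

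**Figure D2:**
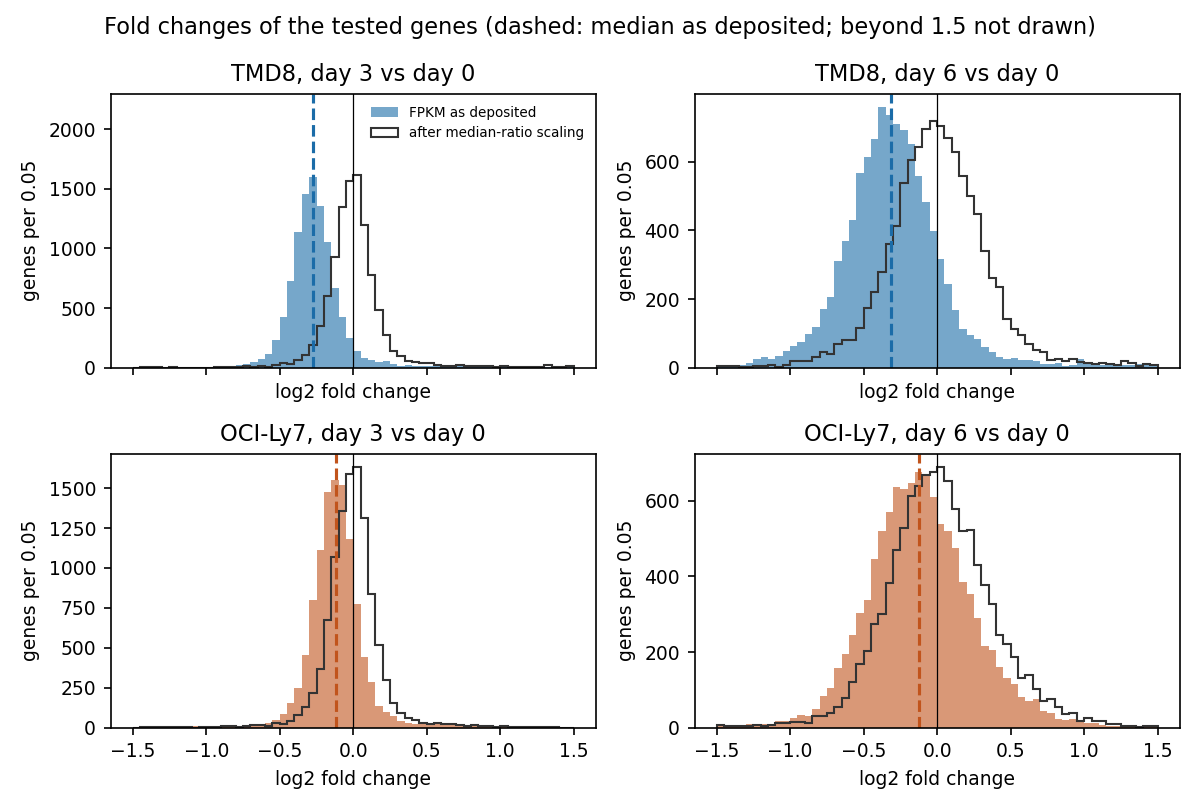
Distribution of log2 changes against day 0 over all tested genes, on FPKM as given and after median-ratio scaling. Changes beyond 1.5 in either direction are not drawn (107 and 184 genes at days 3 and 6 in TMD8, 74 and 106 in OCI-Ly7).

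By day 6 TMD8 had lost transcripts of the sterol pathway, of mitotic genes (27 of 28 lower, 8 after median-ratio scaling) and of several B cell receptor pathway genes (SYK, CD22 and PLCG2), together with MYC, BCL2 and IRF4. The NF-kB targets CCL4, CCL22, CCL3 and IL6 rose in the same cells. On FPKM as given, as many genes of that list were lower as higher. Of 24 p53 target genes 4 were higher and 5 lower (12 higher and 0 lower after median-ratio scaling). Of 18 measured sterol genes, 17 were lower, and 15 after median-ratio scaling. MVD fell from 32.7 ± 0.45 to 7.66 ± 1.1 FPKM (SD, n = 2; log2 change -1.97, adjusted p = 0.001; -1.63 after median-ratio scaling), and DHCR7 changed by -1.21. TOP2A fell from 113 ± 5.9 to 46.8 ± 0.27 FPKM (-1.26, adjusted p = 0.001; -0.90 after median-ratio scaling), next to CENPE (-0.92) and CDC25C (-0.92). MYC fell from 85.8 ± 4.2 to 47.6 ± 8.8 FPKM (-0.85, adjusted p = 0.00383; -0.49 after median-ratio scaling), and BCL2 from 25.5 ± 0.49 to 11.8 ± 1.0 (-1.06, adjusted p = 0.00158; -0.71). IRF4 changed by -0.70 (adjusted p = 0.00426; -0.34 after median-ratio scaling), SYK by -0.78, CD22 by -1.06 and PLCG2 by -0.98, and these 4 also passed after median-ratio scaling. FCGR2B rose by 0.73 (1.01 after median-ratio scaling). CCL4 rose from 16 ± 1.3 to 53.9 ± 4.0 FPKM (1.69, adjusted p = 0.001; 2.04 after median-ratio scaling), with CCL22 (1.47), CCL3 (1.30) and IL6 (1.08). EBI3, another NF-kB target, changed by -0.61 (adjusted p = 0.0029, limma), and by -0.25 after median-ratio scaling (adjusted p = 0.0954). PHLDA3 rose by 0.82 and GADD45A by 0.62, whereas CDKN1A was lower on FPKM as given (-0.20, adjusted p = 0.0402) and turned to 0.16 after median-ratio scaling (adjusted p = 0.196), and CDKN1A did not pass on FPKM as given without any 1 of the 6 libraries (adjusted p from 0.0542 to 0.163). Changes of at least 2-fold were found for 346 genes (147 higher, 199 lower), and after median-ratio scaling for 219 (185 higher, 34 lower). Without the first day 0 library 2402 genes passed; without the second 3965, and without the first day 6 library 4378. Of the 123 named genes that passed, 80 did so in each of the 6 fits that left out 1 library, among them MYC, BCL2, IRF4, SYK, MVD, TOP2A, CCL4 and PHLDA3.

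As groups, the sterol and mitotic genes fell in TMD8 at day 6 relative to the other genes, whereas p53 targets, NF-kB targets, replication genes and splicing factors held up better than the other genes, at the preset correlation and for none of them with an estimated correlation (adjusted p from 0.258 to 0.792). All 18 sterol genes were lower when p-values were adjusted over the list alone. In TMD8 at day 6 the camera test at the preset correlation passed for cholesterol synthesis (lower, median log2 change -0.88, adjusted p = 7.14e-06; adjusted p = 0.258 with an estimated correlation). It also passed for G2/M (lower, -0.56, adjusted p = 6.67e-05; adjusted p = 0.754 with an estimated correlation) and p53 targets (higher, median 0.001, adjusted p = 7.14e-06; adjusted p = 0.643 with an estimated correlation). Of the 28 G2/M genes 27 were lower, 27 over the list alone and 8 after median-ratio scaling. Of the 24 p53 targets 4 were higher and 5 lower, 4 and 2 over the list alone, and 12 and 0 after median-ratio scaling. NF-kB targets were higher against the other genes (adjusted p = 5.78e-05; adjusted p = 0.754 with an estimated correlation) although their median was -0.03 with a mean of 0.10. Of these targets 6 of 23 were higher and 6 lower, the same over the list alone, and 12 and 2 after median-ratio scaling. G1/S genes had a negative median (-0.12) and mean (-0.13) and ranked higher than the other genes (adjusted p = 0.0178; adjusted p = 0.792 with an estimated correlation). Of the 30 replication genes 2 were higher and 11 lower, 2 and 5 over the list alone, and 15 and 2 after median-ratio scaling. Sm proteins and splicing factors likewise had a negative median (-0.05) and ranked higher (adjusted p = 0.000666; adjusted p = 0.754 with an estimated correlation). Among these 26 genes 2 were higher and 3 lower, 2 and 2 over the list alone, and 13 and 0 after median-ratio scaling. SMN1 rose from 6.18 ± 1.2 to 19.2 ± 1.8 FPKM (SD, n = 2; adjusted p = 0.00242). MYC and ribosome biogenesis genes did not pass on FPKM as given (adjusted p = 0.0783; adjusted p = 0.792 with an estimated correlation), with a median of -0.14 that turned to 0.21 after median-ratio scaling, where the list passed (adjusted p = 0.000472; adjusted p = 0.539 with an estimated correlation). B cell receptor genes were lower in 22 of 28 cases and higher in 2, the same over the list alone (adjusted p = 0.254; adjusted p = 0.792 with an estimated correlation). After median-ratio scaling 4 were lower and 5 higher (adjusted p = 0.549; adjusted p = 0.691 with an estimated correlation). With an estimated correlation none of the 21 lists passed in either line at day 6. The smallest adjusted p was 0.258 in TMD8 and 0.939 in OCI-Ly7, and 1 and 0 lists had an unadjusted p under 0.05.

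**Figure D3:**
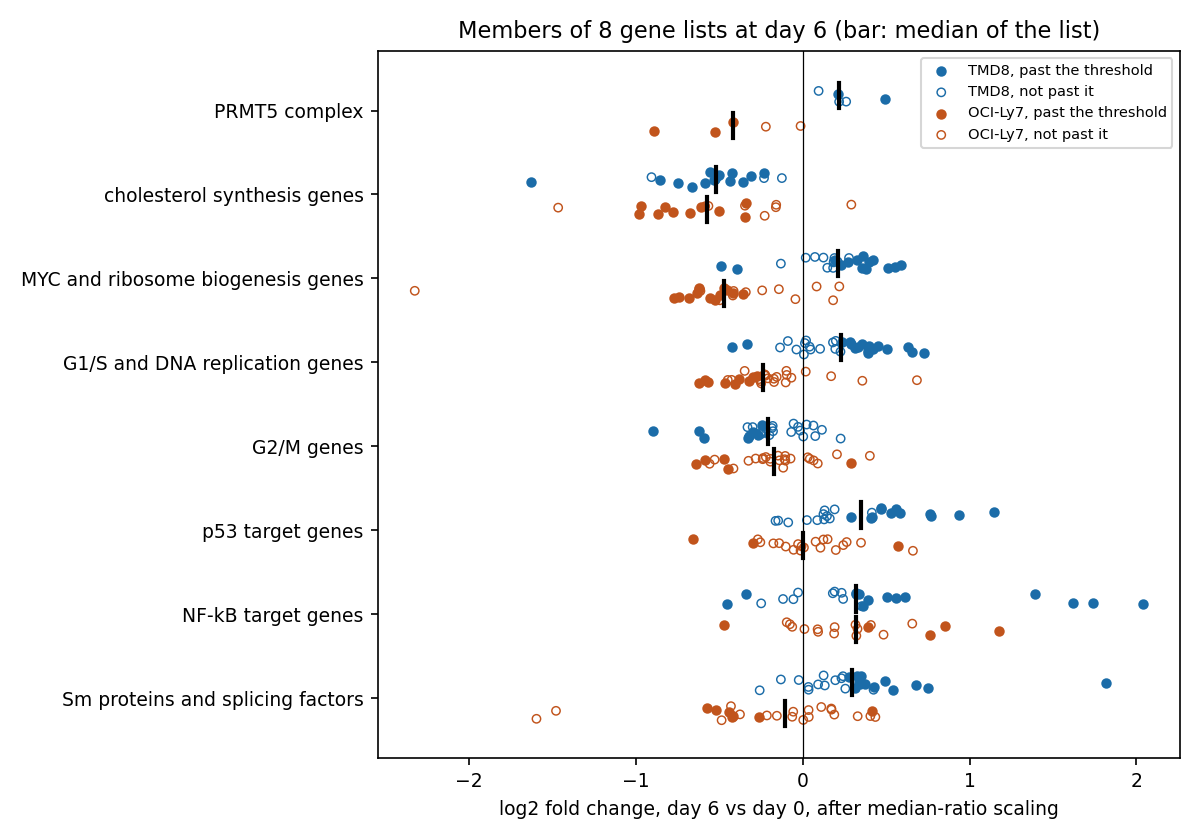
Log2 changes of the members of 8 gene lists at day 6 after median-ratio scaling, with the median of each list. On FPKM as given, the TMD8 medians of the PRMT5 complex, MYC, G1/S, NF-kB and Sm protein lists and the OCI-Ly7 median of the p53 list were negative.

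At day 3 in TMD8, p53 targets ranked above and mitotic genes below the other genes, while few single genes passed after median-ratio scaling. There 23 of 10456 genes passed and 1321 had an unadjusted p under 0.05 (limma), so more genes may have changed than passed. Between days 3 and 6, 13 sterol genes fell and 8 NF-kB targets rose. The p53 targets ranked higher at day 3 (adjusted p = 1.13e-08; adjusted p = 0.384 with an estimated correlation). Their median of -0.02 turned to 0.27 after median-ratio scaling, with 3 higher and 2 lower, 2 and 1 over the list alone, and 1 higher after median-ratio scaling. The G2/M genes ranked lower (adjusted p = 2.78e-05; adjusted p = 0.754 with an estimated correlation), with 26 of 28 lower on FPKM as given (27 over the list alone) and 0 after median-ratio scaling, where 4 were lower at an unadjusted p under 0.05. Cholesterol synthesis, glycolysis and stress response genes ranked lower as well (adjusted p = 0.0195 for each), as did the MYC list (adjusted p = 0.0251); with an estimated correlation the adjusted p was 0.384, 0.798, 0.384 and 0.798. The cholesterol and MYC lists did not pass after median-ratio scaling (adjusted p = 0.0992 and 0.318), where the Sm protein list ranked higher (adjusted p = 0.0221; adjusted p = 0.551 with an estimated correlation). Between days 3 and 6, 820 genes passed (353 higher, 467 lower), against 1219 after median-ratio scaling (686 higher, 533 lower) and 1332 after rescaling to an equal sum (173 higher, 1159 lower). Cholesterol synthesis was the list with the smallest p (lower, adjusted p = 5.67e-10; adjusted p = 0.115 with an estimated correlation), with 13 genes lower (16 over the list alone, 10 after median-ratio scaling). NF-kB targets ranked higher in the same interval (adjusted p = 1.41e-06; adjusted p = 0.684 with an estimated correlation), with 8 genes higher (11 over the list alone, 10 after median-ratio scaling). The G1/S, MYC and Sm protein lists (adjusted p = 1.41e-06, 2.1e-06 and 7.53e-05) and the PRMT5 complex (adjusted p = 0.0272) ranked higher too, and G2/M lower (adjusted p = 0.0365; 0.116 after median-ratio scaling). For each of these 5 lists adjusted p = 0.684 with an estimated correlation. With an estimated correlation none of the 21 lists passed in either of these comparisons, and 2 and 1 had an unadjusted p under 0.05. BTK at day 3 changed by -0.59 and BCL6 by -0.56 on FPKM as given, and neither passed after median-ratio scaling (adjusted p = 0.139 and 0.262). GJA9-MYCBP rose from 0.0211 ± 0.012 to 3.90 ± 0.23 FPKM at day 3 (SD, n = 2; 2.26, adjusted p = 0.0014) and returned at day 6, where the log2 change against day 3 was -2.25. MYCBP and P2RY8 were listed at 0 in both libraries of day 3. Without the filter on mean FPKM the counts were 2705 at day 3 and 359 between days 3 and 6. Leaving out a library took the day 3 count from 4492 to 30 and 39 (first and second day 0 library) and to 32 and 65 (first and second day 3 library), while leaving out a day 6 library gave 5821 and 5783. The count between days 3 and 6 went from 820 to 41 and 37 without the first or the second day 3 library, to 203 and 287 without a day 0 library and to 370 and 420 without a day 6 library.

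In OCI-Ly7 at day 6 MYC fell, together with genes of ribosome biogenesis such as NOLC1 and sterol genes such as MSMO1. Some DNA replication and mitotic genes were lower, among them RRM2 and CCNB1, and the NF-kB targets EBI3 and TRAF1 rose. MYC fell from 116 ± 1.6 to 71.0 ± 1.6 FPKM (SD, n = 2; -0.70, adjusted p = 0.0345; -0.55 after median-ratio scaling), with NOLC1 (-0.89), ODC1 (-0.92), MRTO4 (-0.83) and WDR43 (-0.78). Among sterol genes MSMO1 changed by -1.12 and FDFT1 by -0.97. Replication and mitotic genes included RRM2 (-0.77), CCNE2 (-0.73), RFC3 (-0.72), CCNB1 (-0.74) and DLGAP5 (-0.79). PSAT1 fell from 28.4 ± 1.4 to 12.1 ± 1.2 FPKM (-1.17, adjusted p = 0.0345) and HSPA5 by 0.85. EBI3 rose from 8.08 ± 0.79 to 17.7 ± 3.1 FPKM (1.04, adjusted p = 0.0345) and TRAF1 by 0.72 and CD44 by 0.59; BTK changed by -0.62 (adjusted p = 0.0408). Metallothionein MT2A rose from 32.5 ± 0.013 to 103 ± 12 FPKM (1.63, adjusted p = 0.0252) and CDKN2A from 8.36 ± 0.84 to 26.4 ± 7.2 (1.53, adjusted p = 0.0345). BCL2 changed by 0.14 (adjusted p = 0.352) and BCL6 by 0.42 (adjusted p = 0.0653), and both passed after median-ratio scaling (0.30, adjusted p = 0.038, and 0.57, adjusted p = 0.0269). Of the 1252 genes, 92 changed by at least 2-fold (38 higher, 54 lower), against 104 after median-ratio scaling (69 higher, 35 lower), 121 after rescaling to an equal sum (79 higher, 42 lower) and 142 with a pseudocount of 0.1 (64 higher, 78 lower). Without the filter on mean FPKM 41 passed, and MYC, PSAT1, EBI3 and CDKN2A did not, while MT2A did. With 1 library in a group the OCI-Ly7 count fell to 40 and 16 without the first or the second day 0 library and to 35 and 26 without the first or the second day 6 library. Of the 89 named genes that passed, 9 did so in each fit that held them, among them CSNK1A1, HMGN2P46, MRPL42, NDUFA5, SLC16A1, TUBA4A and TXNDC5 in 6 fits and SCARNA16 in 5. MYC, MSMO1, FDFT1 and EBI3 did not pass without a library of day 0 or 6, but their changes stayed at -0.73 to -0.68, -1.26 to -0.98, -1.06 to -0.88 and 0.87 to 1.20.

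As lists in OCI-Ly7 at day 6, MYC and ribosome biogenesis genes were lower (13 of 25, 18 over the list alone, 13 after median-ratio scaling; as given, median -0.62 and camera adjusted p = 1.41e-05; adjusted p = 0.939 with an estimated correlation). Cholesterol synthesis genes were lower in 11 of 18 cases, 14 over the list alone and 10 after median-ratio scaling (as given, -0.69, adjusted p = 1.48e-05; adjusted p = 0.939 with an estimated correlation). G1/S genes were lower in 8 of 30 cases, 22 over the list alone and 9 after median-ratio scaling (as given, -0.39, adjusted p = 0.000152; adjusted p = 0.939 with an estimated correlation). G2/M genes were lower in 5 of 28 cases, 12 over the list alone and 4 (with 1 higher) after median-ratio scaling (as given, adjusted p = 0.00585; adjusted p = 0.939 with an estimated correlation). NF-kB targets ranked higher (3 higher and 1 lower of 19, the same over the list alone, 4 and 1 after median-ratio scaling; as given, adjusted p = 0.00585; adjusted p = 0.939 with an estimated correlation). The PRMT5 complex was lower in 3 of 5 genes, 4 over the list alone and 3 after median-ratio scaling (as given, adjusted p = 0.029; adjusted p = 0.939 with an estimated correlation). Stress response genes were lower in 5 of 19, 8 over the list alone and 4 after median-ratio scaling (as given, adjusted p = 0.0494; adjusted p = 0.957 with an estimated correlation). Plasma cell genes were lower in 3 of 13 cases, 7 over the list alone and 2 after median-ratio scaling (as given, adjusted p = 0.0497; adjusted p = 0.939 with an estimated correlation), and this list did not pass after median-ratio scaling (adjusted p = 0.0733). At day 3 the G1/S list ranked lower (adjusted p = 0.000278; adjusted p = 0.904 with an estimated correlation). So did the G2/M, plasma cell, MYC, glycolysis and B cell receptor lists (adjusted p from 0.00175 to 0.0451; adjusted p = 0.904 with an estimated correlation for each). Of these the MYC and B cell receptor lists did not pass after median-ratio scaling (adjusted p = 0.0558 and 0.276), and the plasma cell list (median -0.17, mean -0.54) had TXNDC5 as its 1 gene past the threshold. NF-kB targets ranked higher at day 3 (adjusted p = 0.00168; adjusted p = 0.904 with an estimated correlation). Between days 3 and 6 the MYC list ranked lower (adjusted p = 1.07e-05; adjusted p = 0.909 with an estimated correlation) with 0 genes past the threshold, 12 over the list alone, 15 at an unadjusted p under 0.05 and 11 after median-ratio scaling. Cholesterol synthesis (adjusted p = 1.07e-05), G1/S (adjusted p = 0.0262) and the PRMT5 complex (adjusted p = 0.0358) ranked lower and B cell receptor genes higher (adjusted p = 0.0358), each with adjusted p = 0.909 with an estimated correlation. With an estimated correlation none of the 21 lists passed in either comparison, and 0 had an unadjusted p under 0.05.

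Few genes passed at day 3 in OCI-Ly7, and they were mostly loci with extreme changes. TXNDC5 went from 24.0 and 31.2 FPKM to 0 and 0.139 at day 3 and to 0.175 and 0 at day 6. HIGD1A rose to 35.4 ± 1.9 FPKM at day 3 from 8.60 ± 0.28 (SD, n = 2; 1.92, adjusted p = 0.00381) and stood at 5.70 ± 0.012 at day 6. MSL2 dropped from 14.2 ± 0.0082 to 1.48 ± 0.38 FPKM (SD, n = 2) and came back to 12.7 ± 0.22 at day 6. Between days 3 and 6, 24 genes passed (11 higher, 13 lower), among them ID1 (1.26 ± 0.16 to 5.39 ± 0.053 FPKM) and ABCG1 (1.33 ± 0.011 to 5.45 ± 0.17 FPKM; SD, n = 2), and 964 after median-ratio scaling (466 higher, 498 lower). Without the first day 0 library 30 genes passed at day 3, and without the first day 3 library 26; between days 3 and 6 the count was 47 without the first day 3 library. HIGD1A, MSL2 and TXNDC5 were among the genes that passed at day 3 in each of the 6 fits.

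Many genes passed at both days in TMD8 and few in OCI-Ly7, where few had passed at day 3. All comparisons against day 0 used the same 2 control libraries. In TMD8, 128 higher and 3214 lower genes passed at both days, against 6.11 and 2240 for independent calls, and 13 and 5 after median-ratio scaling; the changes correlated with r = 0.663, and 2078 passed at both days without the filter on mean FPKM. In OCI-Ly7, 8 higher and 8 lower genes passed at day 3. Of these, 3 higher and 5 lower passed at both days, against 0.158 and 0.751 for independent calls, with r = 0.413. With the shared controls alone, simulated changes correlated with r = 0.511 in TMD8 and 0.506 in OCI-Ly7. The covariance of the changes was 0.0858 in TMD8 and 0.0501 in OCI-Ly7, against 0.014 and 0.026 from the shared controls, and at most 1 gene passed at both days in those simulations. The 2 control libraries of a line cannot be split into separate controls for the days. Without a day 0 or day 3 library the TMD8 genes past at both days were 24, 29, 22 and 45 (first and second day 0 library, then first and second day 3 library). In OCI-Ly7 they were 21 without the first day 0 library.

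Sterol and lipid genes were lower and the chemokine CCL22 was higher in both lines at day 6. In OCI-Ly7 CCL22 lay close to 0, at 0.67 ± 0.097 FPKM at day 0 and 1.69 ± 0.19 at day 6 (SD, n = 2). Across all genes, however, the day 6 changes of the lines had r = 0.007. Genes higher in both lines numbered 11 (5.36 for independent calls) and included SCARNA17, CCL22, GSDMB, LGALS9, HIST1H3B, HIST1H3D, CCR7 and FCRL2. LGALS9 rose by 1.02 in TMD8 and 0.75 in OCI-Ly7, and FCRL2 by 0.47 and 0.79. Genes lower in both lines numbered 503 (528 for independent calls) and included MRPL42, DHCR7, SCD, POLR2A and MSMO1. POLR2A fell from 41.6 ± 3.8 to 20.1 ± 2.9 FPKM in TMD8 (SD, n = 2; -1.02, adjusted p = 0.00266) and changed by -1.04 in OCI-Ly7 (adjusted p = 0.0347). Opposite directions were found for 114 genes (113 for independent calls). After median-ratio scaling 76 were higher in both (89.8 for independent calls), 73 lower in both (114) and 326 opposite (211). Without the filter on mean FPKM 2 were higher and 6 lower in both. With 1 library in a group most of the shared counts fell, while the OCI-Ly7 changes of LGALS9, FCRL2, DHCR7 and MSMO1 stayed at 0.66 to 0.85, 0.77 to 0.81, -0.93 to -0.84 and -1.26 to -0.98. Without an OCI-Ly7 library of day 0 or 6, no gene was higher in both and 3 to 9 were lower in both. Without the first TMD8 day 0 library 4 were higher in both and 187 lower in both, and without the first TMD8 day 6 library 308 were lower in both.

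The lines differed in their response at day 6 around PRMT5 itself, BCL2 and the MYC and ribosome biogenesis list. The list did not pass with an estimated correlation. MYC itself fell in both lines, and its difference between them did not pass on FPKM as given. PRMT5 lost more transcript in OCI-Ly7 than in TMD8 (difference -0.77, adjusted p = 0.01; -0.98 after median-ratio scaling). BCL2 fell in TMD8 and did not pass in OCI-Ly7 (difference 1.20, adjusted p = 0.00122; 1.01 after median-ratio scaling). BCL6 differed by 0.97 (adjusted p = 0.00564) and CCND3 by -0.62 (adjusted p = 0.0143). In all, 2396 genes differed at day 6, 1786 with a higher change in OCI-Ly7 and 610 with a higher change in TMD8, and 10 differed at day 3. After median-ratio scaling 3207 differed at day 6, 1369 and 1838 in turn. OCI-Ly7 stayed the larger side after rescaling to an equal sum (1973 against 666) and without ribosomal, small RNA and histone genes (1896 against 987). MYC and ribosome biogenesis genes had a median difference of -0.53 (camera adjusted p = 1.72e-07; adjusted p = 0.756 with an estimated correlation), and 11 of 25 genes passed. G1/S genes (-0.19, adjusted p = 4.72e-05; adjusted p = 0.856 with an estimated correlation) and Sm proteins and splicing factors (-0.19, adjusted p = 0.000532; adjusted p = 0.756 with an estimated correlation) also had lower changes in OCI-Ly7 than in TMD8. So did the PRMT5 complex (-0.43, adjusted p = 0.00325; adjusted p = 0.756 with an estimated correlation) and p53 targets (-0.10, adjusted p = 0.0405; adjusted p = 0.856 with an estimated correlation). These 5 lists also passed after median-ratio scaling. At day 3 p53 targets (adjusted p = 1.1e-06; adjusted p = 0.762 with an estimated correlation, and 0.0321 after median-ratio scaling) ranked lower in OCI-Ly7 than in TMD8. Plasma cell genes also ranked lower (adjusted p = 0.000764; adjusted p = 0.605 with an estimated correlation), but their median difference was 0.039 (-0.12 after median-ratio scaling) and TXNDC5 was the 1 gene that passed. NF-kB targets ranked higher (adjusted p = 0.000895; adjusted p = 0.974 with an estimated correlation). The count of 2396 was 1391 with a mean FPKM of at least 5, 1012 without the first TMD8 day 0 library, 1322 without the second, 1524 without the first TMD8 day 6 library, 1533 and 1251 without the first or second OCI-Ly7 day 0 library, and up to 2848 without another library. The count of 10 at day 3 was 32 and 29 without the first OCI-Ly7 library of day 0 or 3, 18 and 23 without the second, and 18 without the first TMD8 day 3 library.

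Histone genes and several classes of small RNA rose in TMD8 by day 6. At day 3, 51 of 59 histone genes were already higher on FPKM as given (median change 1.26). After median-ratio scaling 2 passed at day 3, with a median of 1.5. At day 6, 57 of 59 histone genes were higher in TMD8 (58 after median-ratio scaling), with a median change of 1.34, against 2 of 55 in OCI-Ly7 (6 after median-ratio scaling, 12 at an unadjusted p under 0.05). H/ACA small nucleolar RNAs were higher in 35 of 68 cases, C/D small nucleolar RNAs in 48 of 102 and Cajal body RNAs in 13 of 17 (33, 47 and 11 after median-ratio scaling). In OCI-Ly7 they were higher in 0 of 78, 0 of 123 and 2 of 20 cases and lower in 1, 4 and 1. At an unadjusted p under 0.05, 1, 1 and 5 were higher and 7, 14 and 2 lower. The difference between the lines passed, with the higher change in TMD8, for 21 histone genes of 54, 8 H/ACA RNAs of 68, 11 C/D RNAs of 93 and 3 Cajal body RNAs of 17 (with 1 in the other direction), so it did not pass for most of the small RNAs. Without the first TMD8 day 0 library the higher genes were 35 histone genes, 13 H/ACA, 33 C/D and 6 Cajal body RNAs, without the second 23 H/ACA RNAs, and without the first day 6 library 19 H/ACA RNAs. RMRP went from 940 ± 224 to 5351 ± 614 FPKM in TMD8 (SD, n = 2; 2.52, adjusted p = 0.00346), and RPPH1 and HIST1H4D rose by 2.41 and 2.49. Among the 12 named higher genes of TMD8 were also ROCK1P1, CHURC1-FNTB, SCARNA5, SCARNA21, SCARNA10, SCARNA6, SNORA34, SNORA63 and SNORA80B.

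Several loci switched almost wholly on or off, and for these a fold change carries little meaning. In TMD8, CD99 stood at 34.0 and 32.8 FPKM at day 0 and 26.5 and 28.0 at day 3 and was listed at 0 in both libraries of day 6. In OCI-Ly7, EIF4A1 went from 540 and 591 FPKM to 370 and 427 at day 3 and 39.0 and 0 at day 6, while the read-through gene SENP3-EIF4A1 went from 0.303 and 0.327 to 57.2 and 1.18 and then to 128 and 142. MEF2B went from 60.3 and 57.9 FPKM to 49.5 and 1.98 and then to 1.73 and 0.084, and MEF2BNB-MEF2B rose. The other named lower genes of TMD8 included GTF2H2C_2, YTHDC1, FNTB, FAM203A, BTBD16, UTP14C, CRYL1, DDX39B, TCTEX1D2 and RBM12, and those of OCI-Ly7 included ATF6B, MIR1248, ISY1, SNORD31, MIR6894 and SLC25A11.

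The other lists showed how far the common shift reached. In TMD8 at day 6, genes of the activated B cell state (9 of 13 lower, 1 higher), germinal centre (6 of 10 lower), PI3K signalling (12 of 22 lower, 1 higher), G1 cyclins (8 of 13 lower), stress response (14 of 20 lower), glycolysis (12 of 17 lower) and interferon response (10 of 20 lower) lost transcript on FPKM as given. After median-ratio scaling 4, 3, 3, 2, 5, 2 and 5 of them were lower and 3, 1, 2, 3, 4, 2 and 2 higher. Over the list alone 9, 8, 12, 8, 14, 13 and 10 were lower, and camera passed for none (adjusted p from 0.354 to 0.862). Other PRMT genes (5 of 7 lower), the BCL2 family (3 of 13), plasma cell (4 of 13) and BCL6-repressed genes (8 of 17 lower, 1 higher) had medians that turned from negative to positive after median-ratio scaling, where 1, 5, 1 and 5 genes were higher and 1, 2, 2 and 1 lower. They did not pass either (adjusted p from 0.397 to 0.792; over the list alone 5, 3, 4 and 8 were lower). Neither did the PRMT5 complex on FPKM as given, with 1 of 5 genes lower (0 over the list alone; adjusted p = 0.449). After median-ratio scaling 2 of its genes were higher and the list ranked higher (adjusted p = 0.0229; adjusted p = 0.329 with an estimated correlation). Of 3 measured MHC class II genes 0 passed, and 0 had an unadjusted p under 0.05 (adjusted p = 0.698). CYB5R2 (-1.13), MZB1 (-1.05), SERPINA9 (-1.29), TRIB3 (-0.85), IFITM1 (-0.92) and STAT3 (-0.68) were lower under both scalings. In OCI-Ly7 at day 6, B cell receptor genes were higher in 3 and lower in 3 of 29 cases (3 and 5 over the list alone; 8 and 2 after median-ratio scaling; as given, adjusted p = 0.302). Sm proteins and splicing factors were lower in 5 of 26 (9 over the list alone, 6 after median-ratio scaling; as given, adjusted p = 0.128) and p53 targets lower in 2 of 22 (2 over the list alone; adjusted p = 0.985). The PI3K, G1 cyclin, germinal centre, activated B cell, BCL6-repressed, glycolysis and interferon lists had 1 to 3 genes past the threshold, and camera did not pass (adjusted p from 0.0845 to 0.87). The other PRMT, BCL2 family and MHC class II lists had 0 genes past the threshold and 3, 4 and 2 at an unadjusted p under 0.05 (adjusted p = 0.352, 0.197 and 0.352); after median-ratio scaling 0, 3 and 1 passed. The mitochondrially encoded genes had 0 rows in the tables. Marker lists served as a check of the cultures. Of the markers, 0 of 11 T and NK genes were measured in TMD8 and 1 in OCI-Ly7 (CD4, 1.91 FPKM). The tables held 1 measured myeloid gene in each line (CD68, 50.7 FPKM in TMD8 and 1.28 in OCI-Ly7), and 1 and 2 stromal or epithelial genes (CDH1, 14.7 FPKM in TMD8, and EPCAM, 4.9 FPKM in OCI-Ly7).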

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

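The tests weighed below were chosen after the results they measure had been seen, whereas the test of the difference between the lines was chosen before the data were examined.

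The lines differed in 10 genes at day 3 and in 2396 at day 6, by a test of the difference itself. The fold changes below are OCI-Ly7 minus TMD8 on the log2 scale at day 6, and adjusted p-values are from limma. PRMT5 (-0.77, adjusted p = 0.01), WDR77 (-0.58, adjusted p = 0.0244) and CCND3 (-0.62, adjusted p = 0.0143) changed further down in OCI-Ly7 than in TMD8. BCL2 (1.20, adjusted p = 0.00122) and BCL6 (0.97, adjusted p = 0.00564) fell in TMD8 (-1.06 and -0.55) and did not fall in OCI-Ly7 (0.14 and 0.42), and the 5 signs of the difference held after median-ratio scaling. Among lists the medians were -0.43 for the PRMT5 complex, -0.10 for p53 targets, -0.19 for G1/S genes, -0.53 for MYC and ribosome biogenesis genes and -0.19 for Sm proteins and splicing factors. Large differences of single genes were those of CDK2AP1 (2.75, adjusted p = 0.0162), TMPRSS6 (2.49, adjusted p = 0.000683) and TMED8 (2.33, adjusted p = 0.00476) with the higher change in OCI-Ly7. With the higher change in TMD8 they were EIF4A1 (-6.39, adjusted p = 0.0319), MEF2B (-4.59, adjusted p = 0.0497), TXNDC5 (-4.37, adjusted p = 3.12e-05), SCARNA16 (-4.30, adjusted p = 0.00333) and SCARNA5 (-2.99, adjusted p = 0.0321). CD99 gave a fitted difference of 9.47 (adjusted p = 0.00711) that depends on the pseudocount, since it was listed at 0 in the 2 OCI-Ly7 libraries of day 0 and the 2 TMD8 libraries of day 6. The smaller loss of PRMT5 transcript in TMD8 leaves open whether the lines differ in their need for PRMT5 or in how much of it they lost, and no test here separates these.

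Most genes in treated TMD8 had a lower FPKM than at day 0. A larger share of 45S pre-ribosomal RNA lowers the FPKM of the other genes, and the shift computed from that share alone came within 0.097 of the observed one in each of the 8 treated libraries of both lines (log2 scale). The match follows from the fixed total of FPKM. It would be the same whether a technical or a biological cause raised the 45S share, so it cannot decide between them. A lower amount of messenger RNA per cell would look the same in FPKM and cannot be told apart from a technical origin, since the tables held 0 spike-in rows. Why the 45S share rose was not tested.

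Histone and small RNA genes rose in treated TMD8. In OCI-Ly7 the histone medians also lay above day 0 in the 4 treated libraries (0.24, 0.92, 0.17 and 0.60 after median-ratio scaling). Carry-over of RNA without poly(A) tails would raise these classes wherever 45S RNA is high, whatever the day. Within days, 4 pairs of libraries had 45S shares at least 3 points apart. In these the library with more 45S RNA had the higher class median in 16 of 16 comparisons. Over all 6 pairs it did so in 18 of 24. Each pair was compared in 4 classes of the same libraries, so the comparisons are not independent. The TMD8 day 3 pair, 0.52 points apart, went the other way in 4 of 4. More cells in S phase would raise replication genes alongside. The median change of the G1/S list in TMD8 at day 6 was 0.23 after median-ratio scaling, against 1.66 for the histone genes. How far each set would rise with more cells in S phase was not measured, so these values cannot decide on it. Between days, however, the first OCI-Ly7 libraries of days 3 and 6 had more 45S RNA than day 0 and lower medians of C/D (-0.22 and -0.29) and H/ACA RNAs (-0.46 and -0.52) on the same scale, so the 45S share alone does not set these classes. Less complete removal of such RNA stays open as a candidate explanation, as do more cells in S phase for the histone genes. An effect of PRMT5 stays open too and was not tested.

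Single genes with very large changes may reflect how fragments were assigned rather than expression. Histone, small RNA and ribosomal RNA genes were set aside here. Of the 25 other genes changed at least 4-fold that could be placed in the annotation, 44% had exons overlapping another gene in the tables, against 22.6% of the remaining genes (Fisher exact p = 0.0159). SENP3-EIF4A1 and TXNDC5 are among those with overlap. So are CHURC1-FNTB with FNTB and GJA9-MYCBP with MYCBP, so the test counted some loci more than once. Of the 19 measured in the other line, 36.8% differed at least 5-fold between the 2 libraries of a day there, against 1.2% of the other genes (Fisher exact p = 1.75e-09). Both values fit assignment between gene models, and no biological explanation was tested for these genes. CD99 had no exon overlap with another gene in the tables, so the first value does not bear on it. The TXNDC5 and CD99 values in particular are not read here as changes of the genes.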

How the results depend on the processing

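The scalings named below as chosen later and the joint removal of 2 OCI-Ly7 libraries were picked after the data were seen. The depth of the libraries was lower after treatment and its absolute value unknown, which limits values close to 0. With 2 libraries per group, many counts were sensitive to single libraries, though not each count to each library. Except where the number of genes or libraries changed, the cause was not tested. Without a filter, 2705 genes passed at day 3 and 359 between days 3 and 6 in TMD8, and 41 at day 6 in OCI-Ly7. It gave 2 higher and 6 lower in both lines and 2078 at both days in TMD8. With a mean FPKM of at least 5, 1391 differed between the lines at day 6. Median-ratio scaling gave 23 (day 3) and 3021 (day 6) in TMD8, 964 between days 3 and 6 in OCI-Ly7, 76 higher and 73 lower in both lines and 18 at both days in TMD8. Rescaling to an equal sum gave 42 (day 3) and 1332 (days 3 to 6) in TMD8 and 533 (days 3 to 6) in OCI-Ly7, with 19 higher and 223 lower in both lines and 34 at both days in TMD8. Rescaling without ribosomal, small RNA and histone rows, chosen later, gave 50, 3091 and 1856 for the 3 TMD8 comparisons and 1199 between days 3 and 6 in OCI-Ly7. It gave 41 higher and 117 lower in both lines and 43 at both days in TMD8. A fit of the 2 compared days alone gave 200 between days 3 and 6 in TMD8. The replicate numbers did not pair the libraries, and a replicate block gave 13 (day 3) and 58 (days 3 to 6) in TMD8, and 733 (day 6) in OCI-Ly7. The block gave 5 for the difference at day 3, 6 higher and 202 lower in both lines, and 9 and 5 at both days in TMD8 and OCI-Ly7. Leaving out both second OCI-Ly7 libraries gave 31 (day 3) and 21 (day 6), 68 for the difference at day 3, and 0 higher and 4 lower in both lines. Leaving out 1 library at a time gave 30 to 5821 (day 3), 2402 to 5909 (day 6) and 37 to 420 (days 3 to 6) in TMD8, 12 to 30, 16 to 1285 and 26 to 47 in OCI-Ly7. It gave 7 to 32 and 1012 to 2848 for the difference at days 3 and 6, 0 to 13 higher and 3 to 525 lower in both lines, and 22 to 4147 and 6 to 21 at both days in TMD8 and OCI-Ly7. Of the list tests, 39 of 126 passed at the preset correlation and 0 with an estimated one, where 4 had an unadjusted p under 0.05. In TMD8 these called changes reversed, and no longer passed, under median-ratio scaling: CD79B 0.089 at day 3 and 0.069 at day 6, CLNS1A 0.088 at day 3, and at day 6 CDKN1A 0.163, LSM4 0.036, PRMT1 0.046, PRMT5 0.096 and TXNDC5 0.016. There BTK 0.195, CCND2 0.292, EIF4A1 0.27 and RIOK1 0.215 passed as higher at day 6, and were lower without passing on FPKM as given. Under the scaling chosen later CD79B 0.11 and CLNS1A 0.11 at day 3 and CDKN1A 0.011 at day 6 reversed. Of the named values, 261 of 354 kept direction and side of the threshold under median-ratio scaling, 305 with a replicate block, 306 with an equal sum, 251 without a filter, 341 without a trend and 348 with a pseudocount of 0.1, and 1543 of 2112 with 1 library left out.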

Other observations

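The gene families below were picked after the results had been seen, and so was GZMB.

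Protein folding genes parted the lines at day 6. In OCI-Ly7 the 8 subunits of the TRiC chaperonin were lower in 8 of 8 cases under both scalings (median -0.68), with CCT4 falling from 162 ± 28 to 72.3 ± 12 FPKM (SD, n = 2; adjusted p = 0.0347, limma). In TMD8 1 of 8 was lower on FPKM as given (median 0.024), and 7 were higher after median-ratio scaling (0.39). The difference between the lines passed for 8 of 8. Among 10 heat shock chaperones, 8 were lower in OCI-Ly7, where HSPA8 fell from 573 ± 97 to 207 ± 14 FPKM (adjusted p = 0.0281). In TMD8 5 were higher (3 to 5 with 1 library left out) and 1 lower, where HSPA8 rose from 601 ± 56 to 897 ± 83 FPKM (adjusted p = 0.00479); the difference passed for 8 of 10. With 1 library in the OCI-Ly7 group of day 0 or 6, fewer genes passed at day 6 in that line. The OCI-Ly7 calls of TRiC genes were 0 without any one of its libraries of days 0 and 6, and those of the chaperones were 1 without the first day 0 library and 0 without the second or either day 6 library, while the difference between the lines passed for 5 to 8 TRiC genes and for 6 to 9 chaperones with each library left out.

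Fatty acid genes moved with the sterol genes. In TMD8, 8 of 9 genes of fatty acid synthesis and desaturation were lower (7 after median-ratio scaling), 8 or 9 with each library left out, with SCD at -1.07, FASN at -1.08 and ACSS2 at -1.33. In OCI-Ly7, 4 of 8 were lower (3 after median-ratio scaling), with SCD at -0.98 and FADS2 at -1.04, and 0 without any one library of days 0 and 6. GZMB, which encodes a granzyme, rose in TMD8 from 141 and 143 FPKM to 194 and 201 at day 3 and 351 and 434 at day 6 (1.46, adjusted p = 0.00143; 1.82 after median-ratio scaling). Of 9 chemokine and cytokine genes in TMD8, 5 were higher and 1 lower, and of 5 in OCI-Ly7, 2 were higher, and 0 without any one library of days 0 and 6. Of 14 core proteasome subunits, 6 were lower in OCI-Ly7 (4 after median-ratio scaling, and 0 without any one library of days 0 and 6). In TMD8 1 was higher and 2 lower, turning to 9 higher after median-ratio scaling.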
